A study of Rattus norvegicus with 12 samples.

How the data were processed

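Dorsal root ganglia, which hold the cell bodies of the sensory neurons of the sciatic nerve, were taken from male Sprague-Dawley rats 0.5, 3, 6 or 9 h after a segment of the sciatic nerve had been removed at the mid-thigh. Per the labels, 24 rats were divided into groups of 6, and 3 arrays were hybridised per time, 12 in all. The labels do not say which rats' RNA went onto which array. The p-values therefore measure the spread between these samples, part of which may be technical. No uninjured group is labelled, so 0.5 h served as the reference.

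Total RNA was extracted with Trizol and purified on RNeasy columns, then amplified and labelled with Cy3 in a low-input kit, per the labels' protocols. The arrays had 1 colour. Per the file headers, Agilent Feature Extraction 10.5.1.1 measured 45018 spots per array, of which 43379 were not controls. The deposited values used here are intensity values per spot on a linear scale, after the scanner software's own background subtraction, per the file headers. The series-wide table that the authors deposited holds the same intensity values (largest difference 0). The labels name no step after this, and scaling between arrays is not given in the sources used here.

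Spots called outliers by the scanner software were left out (76 to 218 per array), as were 1639 control spots, and no spot was saturated. The signal was taken as log2 and the 75th percentile of each array was subtracted, so that a level of 0 is the 75th percentile of that array's probes. Spots of 1 probe were averaged. Of 41012 probes, 34837 were well above background on all arrays of at least 1 time and were kept. Each gene name was represented by its kept probe with the highest mean signal over the 12 arrays, which gave 29623 genes. For 4212 genes another 5214 kept probes existed, and their direction is given for named genes where it differed. Gene names are those of the files. The accessions of 16336 probes (39.8%) matched a table of current gene names (assembly GRCr8), and a current symbol is given beside an old one where it helps. Coordinates are those of the files, on the older assembly rn4 (RGSC v3.4).

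Arrays differed in what they could detect. On the 0.5 h arrays 63.2 to 67.5% of probes were well above background, against 82.3 to 85.3% on the others. Where a gene was not well above background on any array of 1 time, its difference is a bound, written as at least N-fold. This bound is the bright time's mean against the dim time's mean of, per array, the higher of the lowest well-above-background signal and the probe's own signal. No fold is given where the bound was under 1 or where the gene was dim at both times. A bound is not strict where some arrays of the bright time were themselves not well above background. The number of arrays, 3 per time, limits the precision of every comparison.

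Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 arrays, 1 shared estimate of the spread per gene; files were read with the data.table package, version 1.17.8). P-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 was called. A moderated F test asked for any difference over the 4 times. Differences are given as log2 values with their standard error (SE), and levels as mean ± SD of 3 arrays. Gene lists were tested with camera, which compares a list with all other genes (preset correlation between genes 0.01, 29 lists, 145 tests adjusted together). The camera fit with an estimated correlation and the rotation test fry, which asks only whether a list's genes move one way on balance, were alternatives. Each list's count of members that rose or fell is given over all genes and adjusted over the list alone.

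The comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined, except where the closing section says otherwise. The rule took, for each comparison with 0.5 h, the 8 largest increases and decreases among called genes whose arrays did not overlap between the times. It took 3 each way for 6 h against 3 h and for 9 h against 6 h. It added up to 4 called members of lists that passed or had at least 3 called members, and 15 genes of interest whatever their result. The rule gave 58 to 102 genes per comparison, and the text names some of them. Of the 15, Sprr1a was not found on the array under that name. Names that were only placeholders were left out. A few genes that the rule gave are not reported here.

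The arrays lay on 5 slides, scanned on 3 days. All 0.5 h arrays were on 1 slide and day, all 3 h arrays on another slide, and all 9 h arrays on another slide and day. The 6 h arrays were on 2 slides scanned on the same day as the 3 h slide. For 0.5, 3 and 9 h, slide and time cannot be told apart. Alternatives were normexp background correction, quantile, median and cyclic loess scaling, other probe filters and probe rules, a common detection floor, another variance model, replicate number and slide as blocks, fits of only the times compared, a 2-fold threshold and leaving out each array. On simulated data for 3 h against 0.5 h with 200 of 29444 genes changed, 25.4% of the genes with a log2 change of 0.5, 65.7% with a change of 1 and 86.4% with a change of 2 were found, none with the wrong sign, and 8 unchanged genes were called. The simulated noise was independent between genes and held no slide effect. Far fewer genes were changed than the 6731 called in the data, so these shares need not hold there.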

Results

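Gene expression was measured in rat dorsal root ganglia at 4 times after the sciatic nerve had been cut, 0.5, 3, 6 and 9 h, with 3 arrays per time. The comparisons with 0.5 h ask what had changed by each later time, and those of 6 h with 3 h and of 9 h with 6 h ask when. Of 29623 genes tested, 21390 were well above background on all 12 arrays. The median local background was 64 to 86 intensity units on the 0.5 h arrays and 37 to 45 on the others, and the 75th percentile of the signal was 1814 to 2152. Arrays of the same time correlated at r = 0.983 to 0.996 and arrays of different times at 0.973 to 0.992, taken across genes, and genes are not independent replicates. The first principal component held 39.2% of the variance and the next 16.0%. Of the other probes of called genes, 61.9% had the same direction at 3 h against 0.5 h (212 called the same way and 68 the opposite way), 67.6% at 6 h and 72.6% at 9 h against 0.5 h, 66.3% at 6 h against 3 h and 79.1% at 9 h against 6 h.

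**Figure D1:**
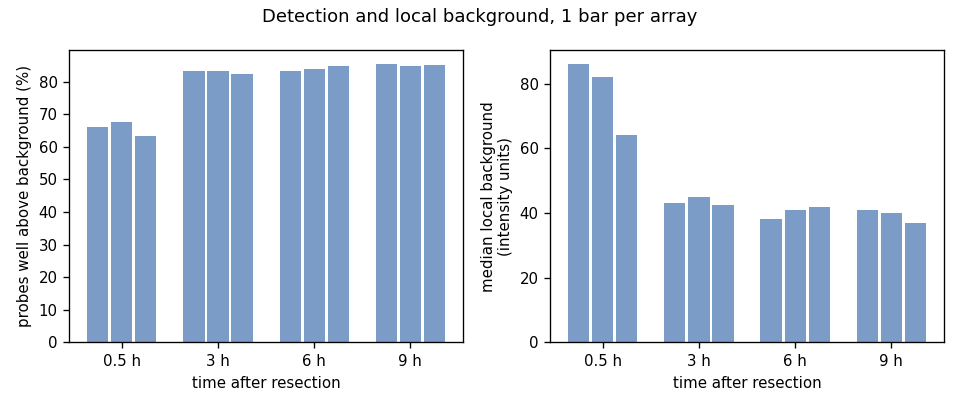
Bars show, for each of the 12 arrays in order of time, the percentage of probes well above background and the median local background in intensity units. The 0.5 h arrays had 63.2 to 67.5% of probes well above background, against 82.3 to 85.3% on the other arrays, and a background of 64 to 86 units against 37 to 45.

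By 3 h after the injury, several target genes of the glucocorticoid receptor, the nuclear receptor for stress steroids, were higher than at 0.5 h. Fkbp5, a chaperone that limits the receptor's own signal, was at 3.03 ± 0.11 (SD, n = 3) at 3 h and 1.72 ± 0.31 at 0.5 h, a rise of 2.49-fold (log2 1.31, SE 0.18, limma adjusted p = 0.001). Zbtb16, a transcriptional repressor, rose 3.11-fold (log2 1.64, SE 0.30, adjusted p = 0.00442), and Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 2.07-fold (log2 1.05, SE 0.20, adjusted p = 0.00541). Of the list's 24 measured members 11 rose, 1 fell and 12 were not called, and 15 rose and 1 fell when adjusted over the list alone. The list's median log2 difference was 0.51, and camera called it (adjusted p = 0.00107, but adjusted p = 0.9994 with an estimated correlation). Pdk4, a kinase that shuts off pyruvate dehydrogenase and a member of this list, was at least 1.06-fold higher (adjusted p = 0.0173), being not well above background on any 0.5 h array. Skeletal muscle and adipocyte markers had median log2 differences of 1.28 and 1.03, which camera did not call (adjusted p = 0.188 for each list), and the number of members called was 0 of 16 (also 0 at an unadjusted limma p under 0.05) and 1 of 7 (3 when adjusted over the list alone). Camera called muscle and fat markers higher without 3 h replicate 3 (adjusted p = 0.00882 and 0.00428) and under normexp (0.00139 and 0.0456). Muscle was also called under normexp with a capped local background (0.0294). The mean level, centred over all arrays, on 3 h replicates 1, 2 and 3 was 1.19, 0.88 and -1.13 for muscle and 0.98, 0.85 and -1.28 for fat.

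The largest increases at 3 h included Ucp3, a mitochondrial carrier abundant in muscle, at least 2.75-fold (adjusted p = 0.0293, not well above background on any 0.5 h array). Epyc, a small proteoglycan of the extracellular matrix, was 3.5-fold higher (log2 1.81, SE 0.54, adjusted p = 0.0389) and Mageh1 3.36-fold (log2 1.75, SE 0.29, adjusted p = 0.00263). Mapt, which encodes the microtubule protein tau, rose 3.25-fold (log2 1.70, SE 0.35, adjusted p = 0.0078). Cyp2e1, a cytochrome P450, was called (adjusted p = 0.0359) without a usable bound. Among the decreases, Gem, a small GTPase induced by activity, fell by 2.78 on the log2 scale (SE 0.31, adjusted p = 0.000277). Gclm, a subunit of the enzyme that makes glutathione's precursor, fell by 2.37 (SE 0.15, adjusted p = 1.28e-05). Pabpnl1 fell by 2.52 (SE 0.18, adjusted p = 2.25e-05). Dlgap2, H1fnt and Fscb were called lower (adjusted p = 0.035, 0.023 and 0.0203). They were well above background on 2, 1 and 1 of the 0.5 h arrays and on no 3 h array, so no usable bound could be given. Rnase11 and the olfactory receptor gene Olr1733 were called lower (adjusted p = 5.59e-05 and 0.000119) but were not well above background at either time.

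Leaving out 1 array ended several of these calls. For Ucp3 these were 0.5 h replicates 1, 2 and 3 and 3 h replicates 1 and 2 (adjusted p = 0.0643 to 0.0979). For Epyc they were the 3 replicates of 0.5 h, 3 h replicates 1 and 2, 6 h replicate 1 and 9 h replicate 1 (0.0513 to 0.117). For Pdk4 they were 0.5 h replicates 2 and 3 and 3 h replicate 1 (0.0527 to 0.0644). For Cyp2e1 they were the 3 replicates of 0.5 h, 3 h replicate 1, 6 h replicate 2 and 9 h replicate 2 (0.0501 to 0.0907). The call for Dlgap2 ended without 0.5 h replicate 1 or 2 or any 3 h array (0.0674 to 0.11), that for H1fnt without 3 h replicate 1 or 3 (0.0698 and 0.0699) and that for Fscb without 3 h replicate 2 or 3 (0.0531 and 0.0536). Gclm, Pabpnl1, Rnase11, S100b, Zfp36 and Per2 belong to 917 genes that fell by 3 h, rose by 6 h and fell by 9 h, a course that 11 of 61 other probes of such genes shared.

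Immediate early genes, the first to answer a stimulus, included more decreases than increases at 3 h: 2 of 38 rose, 7 fell and 29 were not called, the same when adjusted over the list alone (camera adjusted p = 0.376, but 0.043 under normexp). The zinc finger factor Egr1 fell by 1.08 on the log2 scale (SE 0.19, adjusted p = 0.00379). Ier5, not well above background on any 0.5 h array, was called higher (adjusted p = 0.00151) without a usable bound. Zfp36, an mRNA-destabilising protein, was called lower (adjusted p = 0.000738) but was well above background on only 1 array at 0.5 h and 2 at 3 h, and the call ended under normexp and with a common detection floor. Among 34 sensory neuron channels and receptors 4 rose and 3 fell, the same when adjusted over the list alone. Mrgprd, a receptor of nociceptors that end in the skin, fell by 1.34 (SE 0.18, adjusted p = 0.00092). The potassium channel Kcnd3 fell by 0.75 (SE 0.09, adjusted p = 0.000361), while the irritant receptor Trpa1 rose 1.4-fold (log2 0.49, SE 0.11, adjusted p = 0.0119). S100b, a calcium-binding protein of glia, fell by 1.04 (SE 0.10, adjusted p = 0.000112), while 2 of the 15 satellite glia markers rose (3 up and 1 down when adjusted over the list alone).

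Of 34 genes associated with nerve injury and regeneration, 3 rose and 6 fell at 3 h, the same when adjusted over the list alone. Stat3, a factor activated by cytokines of the interleukin-6 family, fell by 0.55 (SE 0.08, adjusted p = 0.00117), but its other probe went the other way. Atf3 and Jun, factors induced in injured neurons, differed by -0.65 (SE 0.22, adjusted p = 0.0603) and -0.16 (adjusted p = 0.211), and Sox11 by -0.22 (adjusted p = 0.392). Il6 was called lower (adjusted p = 0.0245) but was not well above background at either time, its sign turned under quantile and cyclic loess scaling, and the call ended without 0.5 h replicate 1 or 3 or any 3 h array (adjusted p = 0.059 to 0.0737). In the list of STAT3 and acute phase genes 1 of 25 rose and 3 fell (1 each way when adjusted over the list alone). Cebpb, a factor of the acute phase, rose 1.64-fold (log2 0.71, SE 0.09, adjusted p = 0.000533). Of 23 cholesterol synthesis genes 2 rose and 4 fell, the same when adjusted over the list alone, among them Idi1, which fell by 0.37 (SE 0.08, adjusted p = 0.00926). Of 29 oxidative phosphorylation genes 6 rose, such as Uqcrc1 (log2 0.43, SE 0.10) and Ndufa2 (log2 0.41, SE 0.07), and 3 fell, such as Cox5a, which fell by 0.40 (SE 0.09), the same counts when adjusted over the list alone. Of 13 oxidative stress genes 3 rose, Sqstm1 among them (log2 0.46, SE 0.09, adjusted p = 0.00554), and 1, Gclm, fell (5 up and 1 down when adjusted over the list alone). The core clock gene Per2 fell by 0.66 (SE 0.13, adjusted p = 0.00664), while 2 of the 16 clock genes rose (3 up and 2 down when adjusted over the list alone). The neurotrophic factor Nrtn rose 1.29-fold (log2 0.36, SE 0.08, adjusted p = 0.0133).

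In all, 6731 genes were called between 3 and 0.5 h, 2869 higher and 3862 lower. The share higher depended on the scaling: with each array's median in place of its 75th percentile, 4421 were higher and 2897 lower. In 12023 genes (40.6%) the arrays of the times did not overlap, where chance gives 10%. Under normexp background correction 684 genes were called, and fitting only these times gave 4469.

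At 6 h, several immediate early genes and targets of stress steroids lay below their 0.5 h level. Cyr61 (current symbol Ccn1), a matrix-associated signalling protein, fell by 1.73 on the log2 scale (SE 0.29, adjusted p = 0.00587; -1.21 ± 0.23 against 0.52 ± 0.54, SD, n = 3). Egr2, an early growth response factor, fell by 1.48 (SE 0.23, adjusted p = 0.00457). Of 38 immediate early genes 5 rose and 5 fell, and 8 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.843). Of 24 glucocorticoid target genes none rose and 5 fell, and 3 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.486, but 0.00284 under normexp, and not called with the local background capped). Those that fell included Nfkbia, the inhibitor of NF-kappaB, by 1.22 (SE 0.09, adjusted p = 0.000296), the phosphatase Dusp1 by 1.12 (SE 0.14, adjusted p = 0.00244), Errfi1, an inhibitor of EGF receptor signalling, by 1.03 (SE 0.15, adjusted p = 0.00364), and the kinase Sgk1 by 0.95 (SE 0.16, adjusted p = 0.00662).

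The largest increases at 6 h were all of genes not well above background on any 0.5 h array. Ucp3 was at least 2.66-fold higher (adjusted p = 0.0449) and Akr1c14, a hydroxysteroid dehydrogenase, at least 1.03-fold (adjusted p = 0.0459). For Cyp2e1, Gpr18, Slco2a1, Blk, Btbd16 and Ier5 the bound was under 1, with adjusted p = 0.035, 0.00597, 0.0143, 0.0261, 0.00451 and 0.00245. Among the decreases, Gem fell by 3.09 (SE 0.31, adjusted p = 0.00102) and Dlgap2 by 2.78 (SE 0.75, adjusted p = 0.0368), the latter well above background on 1 array at 6 h and 2 at 0.5 h. The olfactory receptor gene Olr717, well above background on 1 of the 0.5 h arrays and no 6 h array, was called lower (adjusted p = 0.0253) without a usable bound. The other 5 of the 8 largest decreases, the chemosensory receptor genes Olr711, Olr809, V1rm4, Olr496 and Olr532, were not well above background at either time, and their sign turned under normexp.

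Several calls ended without 1 array. For Ucp3 these were the 3 replicates of 0.5 h, 3 h replicates 1 and 2, 6 h replicates 2 and 3 and 9 h replicate 2 (adjusted p = 0.0546 to 0.129). For Cyp2e1 they were any 0.5 h or 6 h array or 9 h replicate 2 (0.052 to 0.104). For Akr1c14 they were any array but 0.5 h replicate 2 and 9 h replicates 1 and 3 (0.0585 to 0.131). The call for Slco2a1 ended without 6 h replicate 1 (0.0513), that for Blk without 0.5 h replicate 1 or 2 (0.0683 and 0.068), and that for Olr717 without any 6 h array (0.051 to 0.0877). For Dlgap2 the arrays were 0.5 h replicates 1 and 2, 3 h replicate 1, any 6 h array and 9 h replicate 2 (0.053 to 0.113).

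Camera called cell cycle genes higher at 6 h (median log2 difference 0.33, adjusted p = 0.00519, but adjusted p = 0.9994 with an estimated correlation). Of 17 members 2 rose and 15 were not called, also when adjusted over the list alone. They were Aurkb, a mitotic kinase well above background on 1 of the 0.5 h arrays (log2 0.89, SE 0.18, adjusted p = 0.0122), and Ccnb1, cyclin B1 (log2 0.57, SE 0.16, adjusted p = 0.0414). The call for Ccnb1 ended without any array but 3 h replicates 2 and 3 and 6 h replicate 1 (0.0515 to 0.105). The list's call ended without 6 h replicate 3 (adjusted p = 0.192) and under cyclic loess scaling, and fry did not call it (adjusted p = 0.273). On 6 h replicates 1, 2 and 3 the list's mean level, centred over all arrays, was -0.05, 0.06 and 0.49, that of neutrophil markers -0.44, -0.40 and 1.75, that of red blood cell markers -0.30, -0.13 and 1.20 and that of lymphocyte markers -0.14, -0.05 and 0.51. Skeletal muscle markers were also called higher (median 1.38, adjusted p = 0.0172, but adjusted p = 0.9994 with an estimated correlation), although 0 of the 16 were called by limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. All 16 were well above background on every array, and the list's mean level on the 6 h arrays, centred over all arrays, was -0.95, 2.16 and 0.43. Fry did not call the list (adjusted p = 0.441), and the camera call ended under quantile, median and cyclic loess scaling and without 0.5 h replicate 1 (adjusted p = 0.0959), 0.5 h replicate 2 (0.0518) or 6 h replicate 2 (0.231).

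Of 19 pan-neuronal genes 4 fell and none rose, and 5 fell when adjusted over the list alone (camera adjusted p = 0.236, but 9.33e-06 under normexp, and not called with the local background capped). Map2, a dendritic microtubule protein, fell by 0.63 (SE 0.09, adjusted p = 0.00408) and Syt1, a synaptic vesicle protein, by 0.39 (SE 0.08, adjusted p = 0.0121), with 1 of its 2 other probes going the other way. The chaperone Hsp90ab1 fell by 0.45 (SE 0.06, adjusted p = 0.00368), 1 of 3 heat shock genes that fell of 19 (also 3 when adjusted over the list alone). Ccl2, the chemokine that recruits monocytes, rose 1.33-fold (log2 0.41, SE 0.09, adjusted p = 0.0174, but 0.0563 without 6 h replicate 1 and 0.0593 without 6 h replicate 2). Among cytokines, chemokines and adhesion molecules 3 of 21 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. Of the nerve injury list 3 of 34 fell and none rose (2 down when adjusted over the list alone). Sox11 fell by 0.79 (SE 0.17, adjusted p = 0.0151), a sign that turned under normexp, and Atf3 and Jun differed by -0.02 and -0.14 (adjusted p = 0.97 and 0.323). Il6 was called lower (adjusted p = 0.02) but was not well above background at either time, with a sign that turned under normexp, quantile and cyclic loess scaling and a call that ended without 0.5 h replicate 3 (0.0608) or 6 h replicate 3 (0.0712).

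Camera did not call sensory neuron channels, heat shock genes or oxidative phosphorylation genes at 6 h, but under normexp it called them lower against 0.5 h (adjusted p = 0.00139, 0.000216 and 0.000671). The same held for cholesterol synthesis genes (1.42e-05) and endoplasmic reticulum and amino acid stress genes (0.00978). With the local background capped, camera called none of these lists there. It called lymphocyte markers higher without a filter on dim probes (0.0488) and without 6 h replicate 1 (0.0178) or 2 (0.0419).

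In all, 3963 genes were called at 6 h against 0.5 h, 1206 higher and 2757 lower. Quantile scaling gave 2097 higher and 1816 lower, median scaling 2371 and 1710, and cyclic loess 3540 and 2974. The arrays of the times did not overlap in 10962 genes (37.0%), where chance gives 10%. The count fell to 2565 without 0.5 h replicate 2, 2203 without 6 h replicate 1 and 2165 without 6 h replicate 3, and under normexp only 1 gene was called.

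At 9 h several nerve injury genes were higher than at 0.5 h. Atf3, the transcription factor most used as a mark of injured sensory neurons, was at 3.56 ± 0.13 (SD, n = 3) against 1.73 ± 0.50 at 0.5 h, a rise of 3.56-fold (log2 1.83, SE 0.22, adjusted p = 0.000381). Sox11, a factor needed for axon regrowth, rose 2.92-fold (log2 1.55, SE 0.17, adjusted p = 0.000231), Reg3b, a secreted lectin, 3.14-fold (log2 1.65, SE 0.27, adjusted p = 0.00179) and Jun 1.49-fold (log2 0.58, SE 0.09, adjusted p = 0.00101). Of 34 measured members 11 rose, 1 fell and 22 were not called, and 12 rose and 2 fell when adjusted over the list alone. The median log2 difference was 0.17. The rotation test fry found a shift of the list upward (adjusted p = 0.00217), but camera, which compares the list with other genes, did not call it (adjusted p = 0.322, but 0.0494 under normexp with a capped local background).

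Several inflammatory genes rose as well. Ccl2 rose 2.05-fold (log2 1.04, SE 0.09, adjusted p = 8e-05). Il10, an anti-inflammatory cytokine, was called higher (adjusted p = 0.000625) without a usable bound. Of 21 cytokines, chemokines and adhesion molecules 8 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone (fry adjusted p = 0.0209, camera adjusted p = 0.202, but 0.0456 under normexp). Of 25 STAT3 and acute phase genes 8 rose and none fell, and 10 rose and 1 fell when adjusted over the list alone (fry adjusted p = 0.0106, camera adjusted p = 0.264). They included Socs1 (2.12-fold, log2 1.08, SE 0.11, adjusted p = 0.000153, well above background on 2 of the 0.5 h arrays) and Socs3 (1.86-fold, log2 0.90, SE 0.14, adjusted p = 0.00142), which both curb cytokine signalling. Il6, not well above background on any 0.5 h array, was not called (adjusted p = 0.0827).

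**Figure D2:**
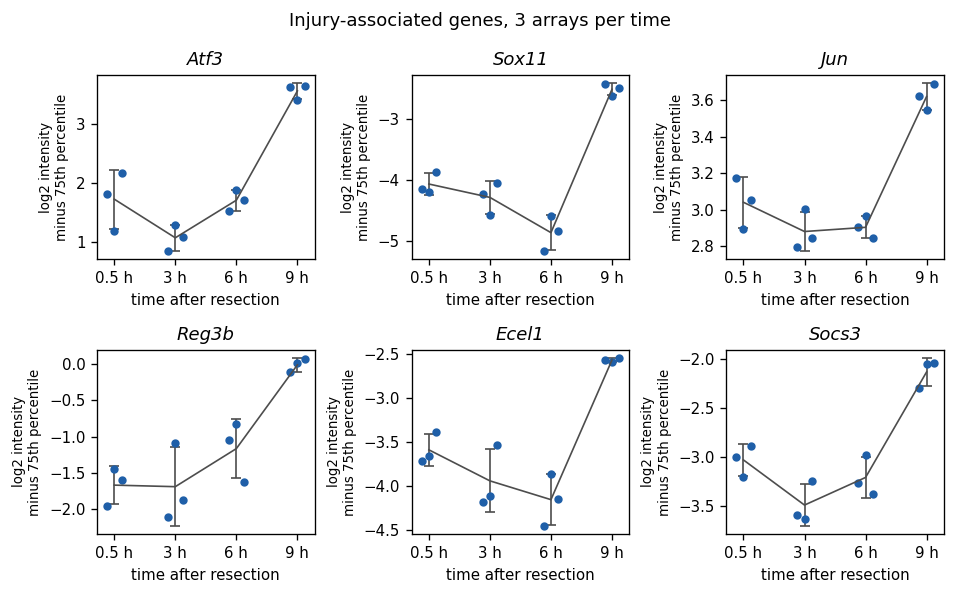
Points show the 3 arrays of each time for Atf3, Sox11, Jun, Reg3b, Ecel1 and Socs3, lines join the means and bars are SD, with hours after injury on the horizontal axis and log2 intensity minus the array's 75th percentile on the vertical axis. Atf3 was at 1.73, 1.07, 1.71 and 3.56 at the 4 times.

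The largest increases at 9 h were of genes not well above background on any 0.5 h array. Vom2r79, a vomeronasal receptor gene, was at least 2.03-fold higher (adjusted p = 0.000671). The olfactory receptor genes Olr252, Olr150, Olr1346 and Olr1491 were at least 2.53-fold, 1.53-fold, 1.74-fold and 1.25-fold higher (adjusted p = 0.000656, 0.00222, 0.00131 and 6.41e-05). Spike-in control probes, which match no rat transcript, had a median log2 signal of -6.74 at 9 h, -6.81 at 0.5 h and -8.38 at 6 h, and negative control spots were at -8.94, -6.85 and -9.50. Whether spike-in RNA had been added to the samples is not known. Ucp3 was at least 2.98-fold higher (adjusted p = 0.0184, but 0.0548 without 9 h replicate 1), Cic, a transcriptional repressor, at least 1.39-fold (adjusted p = 0.0076) and Cyp2e1 at least 1.4-fold (adjusted p = 0.0057). Among the decreases, Gem fell by 2.55 (SE 0.31, adjusted p = 0.000361), Apold1, an early gene of endothelium, by 2.53 (SE 0.22, adjusted p = 8.59e-05), and Rgs1, which damps G protein signalling, by 2.13 (SE 0.27, adjusted p = 0.000474). Pabpnl1 fell by 1.97 (SE 0.18), Olr300 by 1.83 (SE 0.15) and Gclm by 1.82 (SE 0.15), with adjusted p = 9.35e-05, 5.74e-05 and 6.11e-05; all 3 were among the genes that fell, rose and fell again. Zfp36, well above background on 1 array of each time, and Rnase11, on none, were called lower (adjusted p = 0.00037 and 9.35e-05), and both signs turned under normexp.

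Of 38 immediate early genes 10 rose, 9 fell and 19 were not called (10 each way adjusted over the list alone, camera adjusted p = 0.486). Egr2 fell by 1.32 (SE 0.23, adjusted p = 0.00219), Cyr61 by 1.26 (SE 0.29, adjusted p = 0.00859) and Egr1 by 0.74 (SE 0.19, adjusted p = 0.0148, but 0.0515 without 0.5 h replicate 3 and 0.054 without 9 h replicate 2), while Ier5 was called higher (adjusted p = 0.000173). Of 16 circadian clock genes 4 rose and 3 fell (5 and 3 when adjusted over the list alone). Nr1d1, a repressor of the clock, fell by 1.40 (SE 0.24, adjusted p = 0.00193). Dbp, a clock output factor, fell by 1.22 (SE 0.19, adjusted p = 0.00117). Glucocorticoid targets went both ways, 3 of 24 up and 4 down, the same when adjusted over the list alone. Hif3a rose 1.75-fold (log2 0.80, SE 0.12), while Dusp1, Nfkbia and Errfi1 fell by 1.23, 0.81 and 0.76 (SE 0.14, 0.09 and 0.15). Fkbp5 was back near its 0.5 h level (0.09, SE 0.18, adjusted p = 0.735).

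Markers of other cell types also moved at 9 h. Of 7 adipocyte markers 3 rose, Cidec (at least 2.62-fold, adjusted p = 0.0267, but 0.0672 to 0.0787 without 0.5 h replicate 1 or 2 or 9 h replicate 1 or 2), Pck1 (log2 1.16, SE 0.19, well above background on 1 of the 0.5 h arrays) and Lipe (log2 0.57, SE 0.08), and the same number when adjusted over the list alone (fry adjusted p = 0.0411, camera adjusted p = 0.188). The list's mean level, centred over all arrays, was 1.27, 0.73 and -0.30 on 9 h replicates 1, 2 and 3. That of skeletal muscle markers was 0.48, 0.42 and -1.03 on the same arrays. Their median log2 difference was 1.02, with no member called (camera adjusted p = 0.843). Of 15 endothelial and mural cell markers 4 rose, among them Flt1 (log2 0.77, SE 0.11) and Cdh5 (log2 0.50, SE 0.09), and none fell (3 up when adjusted over the list alone). Of 15 lymphocyte markers 4 rose, among them Gzmb (log2 0.84, SE 0.15, adjusted p = 0.00276) and Cd5 (adjusted p = 0.00334, no usable bound), and none fell (3 up when adjusted over the list alone, camera adjusted p = 0.264). The satellite glia markers S100b and Ednrb fell by 0.90 (SE 0.10) and 0.44 (SE 0.10), while 2 of the list's 15 rose, the same when adjusted over the list alone. Of 19 pan-neuronal genes 4 fell (3 when adjusted over the list alone), Map2 by 0.78 (SE 0.09, adjusted p = 0.000361). Of 20 growth factors and ligands 5 rose and 1 fell (4 and 1 when adjusted over the list alone). Areg, an EGF receptor ligand well above background on 1 of the 0.5 h arrays, rose 2.62-fold (log2 1.39, SE 0.20, adjusted p = 0.000929) and Nrtn 1.53-fold (log2 0.61, SE 0.08). Of 19 heat shock genes 3 rose and 2 fell (4 and 3 when adjusted over the list alone), Hsp90ab1 by 0.59 (SE 0.06), with 1 of its 2 other probes going the other way. Of 23 cholesterol synthesis genes 7 rose and 1 fell (8 and 1 when adjusted over the list alone), with Mvk and Dhcr7 at log2 0.36 and 0.37 (SE 0.07 for each). Of 17 cell cycle genes 3 rose, Mcm5 among them (log2 0.64, SE 0.13), and of 13 oxidative stress genes 2 rose, Hmox1 among them (log2 0.51, SE 0.08), and 1 fell. Of 17 hypoxia and glycolysis genes 3 rose and 1 fell. For these last 3 lists the counts were the same when adjusted over the list alone (hypoxia: fry adjusted p = 0.00609, camera adjusted p = 0.766).

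Under normexp camera called sensory neuron channels, pan-neuronal genes, satellite glia markers and heat shock genes lower at 9 h (adjusted p = 0.0462, 0.00361, 0.0203 and 0.00117). It also called oxidative phosphorylation genes (4.83e-06) and endoplasmic reticulum and amino acid stress genes (0.00928) lower there. With the local background capped, camera called none of these lists at 9 h.

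In all, 9881 genes were called at 9 h against 0.5 h, 6718 higher and 3163 lower. Quantile scaling gave 4890 higher and 4567 lower, median scaling 4364 and 4952, and cyclic loess 6307 and 4676. Median scaling moved the median log2 difference of all genes from 0.104 to -0.00911. Among the genes well above background on all arrays 3467 were higher and 2953 lower, and among the others 3251 and 210. The arrays of the times did not overlap in 14372 genes (48.5%), where chance gives 10%, and under normexp 422 genes were called.

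From 3 to 6 h several glucocorticoid targets fell. Zbtb16 fell by 1.90 on the log2 scale (SE 0.30, adjusted p = 0.0034; -3.62 ± 0.34 against -1.72 ± 0.22, SD, n = 3) and Klf15, a metabolic transcription factor, by 1.29 (SE 0.19, adjusted p = 0.00226). Nfkbia fell by 1.27 (SE 0.09, adjusted p = 2.46e-05), Ddit4, an inhibitor of mTOR signalling, by 1.22 (SE 0.15, adjusted p = 0.000905), and Fkbp5 by 0.99 (SE 0.18, adjusted p = 0.00746). Of 24 members none rose, 12 fell and 12 were not called, and 17 fell when adjusted over the list alone. The median log2 difference was -0.62 (camera adjusted p = 5.34e-08, but adjusted p = 0.9994 with an estimated correlation; fry adjusted p = 0.00352).

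**Figure D3:**
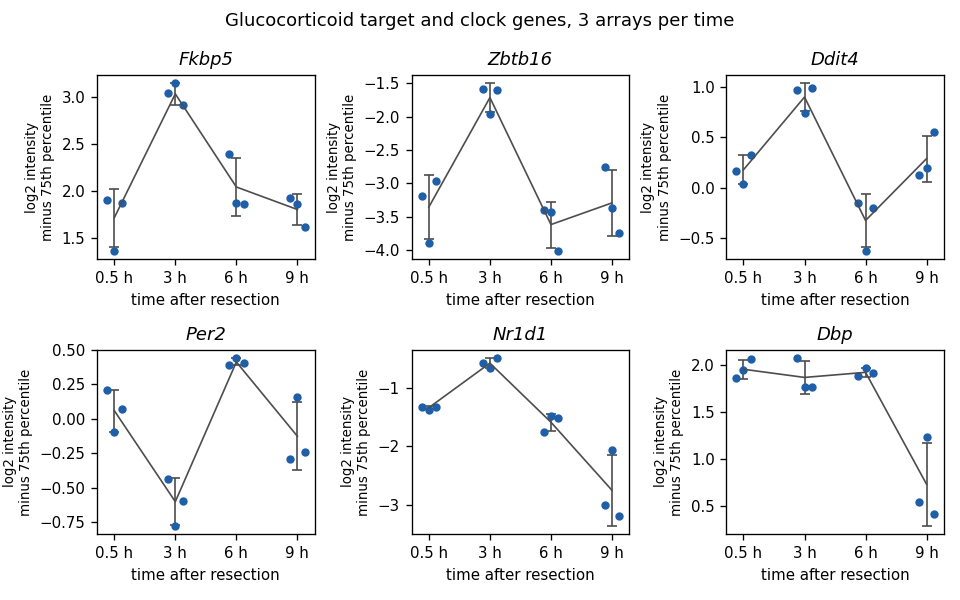
Points show the 3 arrays of each time for Fkbp5, Zbtb16, Ddit4, Per2, Nr1d1 and Dbp, lines join the means and bars are SD, with hours after injury on the horizontal axis and log2 intensity minus the array's 75th percentile on the vertical axis. Fkbp5 was at 1.72, 3.03, 2.04 and 1.81 at the 4 times, and Dbp at 1.95, 1.87, 1.92 and 0.73.

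Several genes of the list of cytokines, chemokines and adhesion molecules rose over the same interval. Sele, an endothelial adhesion molecule, rose 3.41-fold (log2 1.77, SE 0.25, adjusted p = 0.0017), the neutrophil chemokine Cxcl1 3.29-fold (log2 1.72, SE 0.29, adjusted p = 0.00511) and Ccl2 1.6-fold (log2 0.68, SE 0.09, adjusted p = 0.00128). Of 21 cytokines, chemokines and adhesion molecules 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0856). Camera called this list higher under normexp (0.0209) and normexp with a capped local background (0.0297), without a filter on dim probes (0.0379), with probes well above background on all arrays (0.0376), and with the mean of kept probes (0.0407). It also did so with replicate number as a block (0.0288), with a common detection floor (0.0377) and without 3 h replicate 2 (0.0406), 3 h replicate 3 (0.0236), 6 h replicate 1 (0.0472) or 9 h replicate 2 (0.044). Of 20 endoplasmic reticulum and amino acid stress genes 4 fell, Hspa5, the main chaperone of this compartment, by 0.41 (SE 0.09, adjusted p = 0.0145), and 12 fell and 1 rose when adjusted over the list alone (fry adjusted p = 0.0058, camera adjusted p = 0.0856). Camera called them lower under normexp (0.000102), without a filter on dim probes (0.0488), with a common detection floor (0.0347) and without 3 h replicate 2 (0.0428), 6 h replicate 1 (0.044) or 9 h replicate 2 (0.0498). Of 17 hypoxia and glycolysis genes 3 fell (4 when adjusted over the list alone), with Ankrd37 lower by 0.61 and the glucose transporter Slc2a1 by 0.49 (fry adjusted p = 0.00329, camera adjusted p = 0.188, but 0.000357 under normexp). At 3 h against 0.5 h fry called this list higher (adjusted p = 0.00276). Camera did so there only under normexp (0.0023), normexp with a capped local background (0.0075) and without a filter on dim probes (0.0334). The chaperones Hsp90ab1 and Hsp90aa1 fell by 0.42 (SE 0.06) and 0.35 (SE 0.07), and 1 of the 2 other probes of Hsp90ab1 went the other way. Camera called cell cycle genes higher (median 0.28, adjusted p = 0.0308, but adjusted p = 0.9994 with an estimated correlation), although 0 of the 17 were called by limma, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The list's mean level was 0.49 on 6 h replicate 3, where neutrophil and red blood cell markers were at 1.75 and 1.20, and -0.05 and 0.06 on the other 6 h arrays. Fry did not call the list (adjusted p = 0.411), and the camera call ended under normexp, quantile and cyclic loess scaling, with probes well above background on all arrays (adjusted p = 0.066) and without 0.5 h replicate 1 (adjusted p = 0.0565), 3 h replicate 1 (0.0549), 3 h replicate 3 (0.0903) or 6 h replicate 3 (0.443).

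Per2 rose 2.02-fold between 3 and 6 h (log2 1.02, SE 0.13, adjusted p = 0.00105) and the clock repressor Cry1 1.6-fold (log2 0.68, SE 0.11, adjusted p = 0.00447), while the repressor Nfil3 fell by 0.66 (SE 0.11, adjusted p = 0.00449). Dusp6, a phosphatase of ERK kinases, rose 1.65-fold (log2 0.72, SE 0.12, adjusted p = 0.00489), and Egr1 1.61-fold (log2 0.69, SE 0.19, adjusted p = 0.0495, but 0.0523 to 0.149 without any array but 0.5 h replicate 3 and 9 h replicate 3). S100b rose 2.17-fold (log2 1.12, SE 0.10, adjusted p = 0.0001) and Ednrb, an endothelin receptor of glia, fell by 0.56 (SE 0.10, adjusted p = 0.00636). Kcnd3 rose 1.36-fold (log2 0.44, SE 0.09, adjusted p = 0.01). In the nerve injury list 2 of 34 rose and 1 fell, the same when adjusted over the list alone: Klf7, a factor of axon growth, fell by 0.63 (SE 0.08, adjusted p = 0.0013) and Fst, follistatin, rose 1.63-fold (log2 0.71, SE 0.12, adjusted p = 0.00416). Atf3 differed by 0.64 (SE 0.22, adjusted p = 0.104), Sox11 by -0.58 (adjusted p = 0.0592) and Jun by 0.02 (adjusted p = 0.891).

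The largest increases between 3 and 6 h were Rnase11 (at least 2.64-fold, adjusted p = 2.01e-05) and Gclm (5.87-fold, log2 2.55, SE 0.15, adjusted p = 1.1e-05), with Lrig3 (at least 2.06-fold, adjusted p = 0.0237, but 0.0667 to 0.095 without 3 h replicate 1 or 6 h replicate 2 or 3). Rnase11 and Lrig3 were not well above background on any 3 h array. The largest decreases, each well above background on 1 of the 3 h arrays and no 6 h array and so without a usable bound, were Taar7e (adjusted p = 0.0483, but 0.0594 to 0.174 without any array but 0.5 h replicates 1 and 2 and 3 h replicate 2), Olr1199 (adjusted p = 0.0172, but 0.0531 and 0.0574 without 6 h replicate 2 or 3) and Olr496 (adjusted p = 0.00524). All 3 turned sign under normexp. In all, 3075 genes were called, 1756 higher at 6 h and 1319 lower, against 2089 and 965 under cyclic loess. The arrays of the times did not overlap in 10332 genes (34.9%), where chance gives 10%. These times were scanned on the same day, on 3 slides, and a fit of these arrays alone called 2706. The count fell to 1850 without 3 h replicate 1 and 1648 without 6 h replicate 3, and under normexp 320 genes were called.

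Between 6 and 9 h several injury genes rose. Sox11 rose 5.07-fold (log2 2.34, SE 0.17, adjusted p = 1.59e-05; -2.52 ± 0.10 against -4.87 ± 0.29, SD, n = 3), Atf3 3.6-fold (log2 1.85, SE 0.22, adjusted p = 0.000207) and Jun 1.64-fold (log2 0.71, SE 0.09, adjusted p = 0.000198). Ecel1, a protease-like protein of injured neurons, rose 3-fold (log2 1.59, SE 0.19, adjusted p = 0.000194). Il6, not well above background on any 6 h array, was called higher (adjusted p = 0.000685), a call that ended in 2 of 25 alternatives. Its 9 h levels of -6.38, -5.38 and -6.87 lay near the median of the spike-in control probes at 9 h (-6.74). On replicate 3 it was below the lowest well-above-background signal (-6.74), so no fold is given. Signal that needs no rat target was not set apart for this gene. Of 34 members 11 rose, none fell and 23 were not called, the same when adjusted over the list alone (median 0.16, fry adjusted p = 0.00112, camera adjusted p = 0.202, but 0.0203 under normexp and 0.033 under quantile scaling).

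Some inhibitors of cytokine signalling also rose: Socs3 2.1-fold (log2 1.07, SE 0.14, adjusted p = 0.00036), Socs1 2-fold (log2 1.00, SE 0.11, adjusted p = 0.000118) and Cish 1.59-fold (log2 0.66, SE 0.13, adjusted p = 0.00452). In the list of STAT3 and acute phase genes 7 of 25 rose and none fell, and 7 rose and 1 fell when adjusted over the list alone (fry adjusted p = 0.033, camera adjusted p = 0.769). Of the cytokines, chemokines and adhesion molecules 7 of 21 rose and none fell, the same when adjusted over the list alone (fry adjusted p = 0.0375, camera adjusted p = 0.473, but 0.0461 under normexp). Ccl2 rose 1.54-fold (log2 0.63, SE 0.09, adjusted p = 0.000647) and Il10 2.17-fold (log2 1.12, SE 0.18, adjusted p = 0.00115). Among immediate early genes 5 of 38 rose and 1 fell, the same when adjusted over the list alone, including the phosphatases Dusp2 (log2 1.15, SE 0.15) and Dusp4 (log2 0.87, SE 0.16). Il10, Dusp2 and Dusp4 were not well above background on every array. Their calls ended in 3, 1 and 3 of 25 alternatives, with lowest log2 differences of 0.03, 0.56 and 0.14.

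Of 23 cholesterol synthesis genes 9 rose, 1 fell and 13 were not called between 6 and 9 h, and 13 rose and 1 fell when adjusted over the list alone (median 0.22, fry adjusted p = 0.00327, camera adjusted p = 0.118). Camera called the list higher under normexp (0.00722), quantile (0.00715) and cyclic loess scaling (0.0178), with probes well above background on all arrays (0.0157) and with a common detection floor (0.0133). The pathway's enzymes Mvd and Dhcr7 were each at log2 0.44 (SE 0.09 and 0.07, adjusted p = 0.00618 and 0.00184). The clock output gene Dbp fell by 1.19 (SE 0.19, adjusted p = 0.00102) and Nr1d1 by 1.15 (SE 0.24, adjusted p = 0.00512), while Nfil3 rose 1.77-fold (log2 0.83, SE 0.11, adjusted p = 0.000371). Per2, another gene of the course that fell, rose and fell again, fell by 0.54 (SE 0.13, adjusted p = 0.0134, but 0.0507 without 9 h replicate 3). The endothelial genes Flt1 and Cdh5 rose by log2 1.24 (SE 0.11) and 0.59 (SE 0.09), but the other probe of Cdh5 went the other way; 3 of the list's 15 members rose and none fell, the same when adjusted over the list alone (fry adjusted p = 0.033, camera adjusted p = 0.513). Olig2 and Mobp, genes of oligodendrocytes in the list of spinal cord cells, rose 3.06-fold (log2 1.61, SE 0.27, adjusted p = 0.00154) and 2.98-fold (log2 1.57, SE 0.25, adjusted p = 0.0013), and 4 of the list's 11 rose (5 when adjusted over the list alone, camera adjusted p = 0.264). Olig2 was not well above background on every array, and its call ended in 2 of 25 alternatives. Hif3a rose 2.61-fold (log2 1.39, SE 0.12, adjusted p = 3.76e-05). The neurotrophic factor Gdnf rose 1.58-fold (log2 0.66, SE 0.14), Areg 2.1-fold (log2 1.07, SE 0.20) and the potassium channel Kcns1 1.37-fold (log2 0.46, SE 0.11). Of 17 hypoxia and glycolysis genes 3 rose, Egln3 (log2 0.28, SE 0.06) and Pfkfb3 (log2 0.58, SE 0.12) among them, also 3 when adjusted over the list alone (fry adjusted p = 0.00985, camera adjusted p = 0.902). Pfkfb3 was not well above background on every array, and its call ended in 4 of 25 alternatives. In the reported fit camera did not call cell cycle genes over this interval. It called them lower without a filter on dim probes (0.0334), under normexp with a capped local background (0.0294) and with slide as a random block (0.0402). It also did so without 6 h replicate 1 (0.00549) or 2 (0.0428) or 9 h replicate 2 (0.0275).

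The largest increases between 6 and 9 h were the olfactory receptor genes Olr496, Olr1726 and Olr1071, at least 4.61-fold, 5.44-fold and 5.25-fold higher (adjusted p = 2.42e-05, 6.78e-05 and 0.000265), none of them well above background on any 6 h array. Spike-in control probes were brighter by 1.644 and negative control spots by 0.56 over the same interval. The largest decreases were Rnase11 (at least 2.27-fold, adjusted p = 1.65e-05), Gclm, which fell by 2.01 (SE 0.15, adjusted p = 1.79e-05), and Lrig3 (at least 1.77-fold, adjusted p = 0.0174, but 0.0531 to 0.0703 without 6 h replicate 3 or 9 h replicate 2 or 3, with a sign that turned under normexp). In all, 7448 genes were called, 5692 higher and 1756 lower. Quantile scaling gave 3230 higher and 3645 lower, median scaling 3558 and 6069, and cyclic loess 3707 and 2985, so the excess of increases depended on the scaling. Median scaling moved the median of all genes from 0.110 to -0.0990. In the reported fit, 2833 were higher and 1548 lower among genes well above background on all arrays, and 2859 and 208 among the others. The arrays of the times did not overlap in 13045 genes (44.0%), where chance gives 10%, 4515 genes were called among probes well above background on all arrays, and under normexp 163.

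Over the 4 times together the F test called 12919 genes. The largest group was highest at 9 h (6194 genes, 47.9%), and 3122 were highest at 0.5 h, 2262 at 3 h and 1341 at 6 h. The lowest mean was at 6 h in 4404 genes, at 0.5 h in 3454, at 3 h in 3318 and at 9 h in 1743. The most common course was highest at 9 h and lowest at 6 h (3047 genes, 23.6%), followed by highest at 9 h and lowest at 0.5 h (2027) and highest at 0.5 h and lowest at 3 h (1539). Among the 8899 called genes well above background on all arrays, 3023 (34.0%) were highest at 9 h, 1404 were highest at 9 h and lowest at 6 h, and 1386 were highest at 0.5 h and lowest at 3 h. Median scaling turned the split of 9 h against 6 h to 3558 higher and 6069 lower. Several classical genes of later injury did not pass the test in any of the 5 comparisons. The neuropeptide gene Gal was at 3.07, 3.17, 3.02 and 2.96 at the 4 times and Gap43, a growth cone protein, at 5.22, 5.36, 5.22 and 5.39. Npy, which varied widely between arrays, was at 3.08 ± 1.00, 2.29 ± 0.84, 2.64 ± 1.00 and 2.22 ± 0.40 (SD, n = 3). Fos was at -1.07, -1.27, -0.89 and -0.82, and the clock gene Per1 at -0.99, -0.82, -1.76 and -1.38, also without a call. Of 18 neuropeptide genes 2 rose at 3 h against 0.5 h, the same when adjusted over the list alone, and 0 were called at 6 or 9 h against 0.5 h. Between 3 and 6 h 1 of them fell, also when adjusted over the list alone. Between 6 and 9 h 1 rose (0 when adjusted over the list alone). Camera called neuropeptides lower at 6 h against 3 h under normexp (adjusted p = 0.00112) and without 6 h replicate 1 (0.0196). Of 15 myelinating Schwann cell markers 1 fell at 3 h and at 6 h, also when adjusted over the list alone, and at 9 h 2 rose and 1 fell (1 down when adjusted over the list alone). Of 19 macrophage markers 1 rose and 1 fell at 9 h against 0.5 h and 1 fell between 6 and 9 h (0 in both when adjusted over the list alone). Camera called macrophage markers higher at 6 h against 0.5 h under normexp with a capped local background (adjusted p = 0.0294) and without 6 h replicate 1 (0.0178), and higher at 6 h against 3 h without 3 h replicate 3 (0.0148) or 6 h replicate 1 (0.0178). It called them lower at 9 h against 6 h under normexp (0.0461) and without 6 h replicate 1 (0.0263). Of 12 neutrophil markers 1 rose at 9 h against 0.5 h and 1 between 6 and 9 h, also when adjusted over the list alone, and 0 were called at 6 h. Their median log2 difference was 0.79 at 6 h against 3 h (camera adjusted p = 0.101). Camera called them higher there without a filter on dim probes (0.0334), under normexp with a capped local background (0.041), with slide as a random block (0.0402) and without 6 h replicate 1 (0.00583) or 2 (0.00622). At 6 h against 0.5 h it did so under normexp with a capped local background (0.0318) and without 6 h replicate 1 (0.0132) or 2 (0.0337). Of 13 fibroblast markers 1 rose at 9 h (0 when adjusted over the list alone). Without 6 h replicate 1 camera called this list higher at 6 h against 0.5 h (0.0232) and 3 h (0.0102) and lower at 9 h against 6 h (0.0102). Of 20 interferon response genes 1 rose at 6 h and at 9 h against 0.5 h, also when adjusted over the list alone, and the median log2 difference at 9 h was -0.30 (camera adjusted p = 0.206). Camera called the list lower at 9 h against 0.5 h under normexp (0.00528) and without 9 h replicate 1 (0.0106), at 9 h against 6 h under the same alternatives (0.0485 and 0.0173), and at 6 h against 3 h under normexp (0.0456). Of 7 red blood cell markers limma called 0 in each comparison, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05. Camera called them higher at 6 h against 3 h without 6 h replicate 1 (0.044).

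On assembly rn4 the probe for Atf3 lay on chromosome 13 at 107191691 to 107191749, that for Sox11 on chromosome 6 at 45142098 to 45142157, that for Fkbp5 on chromosome 20 at 6637600 to 6637659 and that for Gem on chromosome 5 at 26003029 to 26004574.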

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

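The test with control spots in this part was chosen only after the result was seen, and its rule was rewritten with the differences of both kinds of control spot known, since the first rule, a spike-in difference above 0 by more than 2 SE, was met by probes singled out for it. Spike-in control probes, which match no rat transcript and are used in no comparison above, were singled out because they gave a signal above that at 6 h. Their median log2 signal was -6.81 ± 0.20 at 0.5 h, -8.00 ± 0.23 at 3 h, -8.38 ± 0.21 at 6 h and -6.74 ± 0.30 at 9 h (SD, n = 3). Of their spots, 2.96% were well above background at 0.5 h, 28.0% at 3 h, 27.9% at 6 h and 46.9% at 9 h. For negative control spots these shares were 1.31%, 0.44%, 1.09% and 1.31%. Whether spike-in RNA had been added to the samples is not known, so a difference in its amount was not set apart.

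Olfactory, vomeronasal and other chemosensory receptor genes were higher at 9 h than at 6 h, with 392 of 641 up, 12 down and a median log2 difference of 1.65. A rise of dim probes in general was argued against as the whole cause, since the highest median of 1000 random lists of other genes of the same mean signal was 0.4964. Those lists were matched on the mean over 12 arrays, not on how genes passed the probe filter. Of 119 receptors not well above background on any 6 h array, 113 were so on all 9 h arrays, so selection may add to the difference. Scaling was argued against as the whole cause, since the receptors' median was 1.145 under quantile scaling. Signal on the 9 h arrays that needs no rat target stays open, since the 14 spike-in probes, singled out for this very difference, were higher by 1.644 (SE 0.211) but negative control spots only by 0.56 (SE 0.0964). The spike-in probes may not have been free of target, since it is not known whether spike-in RNA had been added. With a common detection floor 186 receptor genes rose, and of 167 well above background on all arrays 98 rose and 11 fell. A true change of receptor transcripts by 9 h was not tested apart from slide and scan day, which cannot be told apart from time here.

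Other splits of the arrays bear on the counts. For 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real split gave 6731 genes for 3 h against 0.5 h and the highest other 0, 3963 and 1 for 6 h against 0.5 h, 9881 and 9 for 9 h against 0.5 h, 3075 and 0 for 6 h against 3 h, and 7448 and 2 for 9 h against 6 h. In the 5 comparisons 1 split of the 10, the real one, gave as many. For the glucocorticoid list at 6 h against 3 h 1 of 10 splits gave as small an adjusted p (5.34e-08, smallest other 0.0013), and at 3 h against 0.5 h 4 of 10 did (0.00107, smallest other 2.76e-06). Over the 4 times, 1 of 100 splits of the 12 arrays gave as many genes as the real 12919 (highest other 2527), so the count depended on how the arrays were grouped. Other splits break up slides that the real grouping mostly keeps whole. They therefore cannot tell an effect of time from one of slide or scan day. For the number of list calls, all 100 of 100 splits gave at least the real 5 (highest other 58), so chance cannot be excluded.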

How the results depend on the processing

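The alternatives chosen only after the data were seen were normexp with a capped local background, the common detection floor, cyclic loess, and the fits over fewer times. Scan day as a block was not run, since it cannot be fitted beside time. Background correction mattered most. Normexp gave 684 genes for 3 h against 0.5 h, 1 for 6 h against 0.5 h, 422 for 9 h against 0.5 h, 320 for 6 h against 3 h, 163 for 9 h against 6 h and 678 over the 4 times. The median residual SD was 0.1432 in the reported fit, 0.3377 under normexp and 0.1119 with the local background capped, which gave 8228, 6433, 7672, 3282, 7762 and 14166 genes in the same order, so the loss under normexp went with a few spots of very high local background.

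Slide as a random block (correlation of arrays on a slide -0.255) gave 13845, 9072, 16879, 7928, 12504 and 21774. A negative correlation narrows the SE of a mean of arrays on the same slide, which is the layout of 0.5, 3 and 9 h. Only the 6 h arrays spanned 2 slides, so these larger counts do not show that the results stand apart from slide. A 2-fold threshold gave 912, 477, 2277, 594, 2902 and 3846. Without a filter on dim probes, 3 h and 6 h against 0.5 h gave 11482 and 8981, and fits of only the times compared 4469 and 2488. For 6 h against 0.5 h cyclic loess gave 6514, for 9 h against 6 h probes well above background on all arrays gave 4515, and over 0.5, 3 and 6 h alone 7250 genes were called. Fits of fewer times use fewer arrays, and the filters test other sets of genes. Apart from these and the slide fit, the cause was not tested. Leaving out 1 array gave 4508 to 6732, 2165 to 4071, 7771 to 10171, 1648 to 3179, 5401 to 7792 and 10550 to 12509. For 6 h against 0.5 h the count was 2565 without 0.5 h replicate 2, 2203 without 6 h replicate 1 and 2165 without 6 h replicate 3, and for 6 h against 3 h 1850 without 3 h replicate 1 and 1648 without 6 h replicate 3.

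The 5 list calls became 0 with an estimated correlation, 16 with the rotation test, 40 under normexp, 13 without the filter on dim probes, 13 with capped normexp, 8 with the common floor and 3 under cyclic loess. Where camera is said above to call a list under normexp but not under capped normexp, capping the local background ended that call. Leaving out 1 array gave 3 to 21: 3 without 0.5 h replicate 1 or 6 h replicate 3, 8 without 3 h replicate 3 or 6 h replicate 2, 9 without 9 h replicate 2 and 21 without 6 h replicate 1. The glucocorticoid list was called in 26 of 27 alternatives in both comparisons, all but the estimated correlation. The 27 include the deposited series-wide table, whose identical values could not change the result.

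For the 224 gene results in the text, 5758 comparisons with alternatives left 5252 on the same side of the threshold and in the same direction (2 of them with a difference of 0), 406 lost the call, 41 gained one and 59 turned sign, 17 of results called as reported and 42 of results not called, none of which gained a call. Of the 5252, 224 came from the deposited series-wide table, whose values are the same, so they could not differ. Normexp ended 134 calls and the common detection floor 55. Of called results, under normexp the sign turned at 6 h against 0.5 h for Olr711 (0.3205), Olr809 (0.6933), V1rm4 (0.7553), Olr496 (0.465), Olr532 (0.6793), Sox11 (0.0106) and Il6 (0.7262), at 9 h against 0.5 h for Rnase11 (0.7375) and Zfp36 (0.3389), at 6 h against 3 h for Taar7e (0.582), Olr1199 (0.6421) and Olr496 (0.7392), and at 9 h against 6 h for Lrig3 (0.1541). Il6 turned under quantile scaling (0.6988 at 3 h and 0.5776 at 6 h against 0.5 h) and cyclic loess (0.1169 and 0.0894). Except for Sox11, each of these had arrays on which it was not well above background, and the cause was not tested.

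Of results not called, the sign turned under normexp at 9 h against 0.5 h for Gap43 (-0.0573) and Fkbp5 (-0.0277), at 6 h against 3 h for Jun (-0.0516), Sox11 (0.2554), Il6 (0.8228) and Dbp (-0.0217), and at 9 h against 6 h for Gap43 (-0.0168). Median scaling turned it at 6 h against 0.5 h for Atf3 (0.0777), Gal (0.0499), Gap43 (0.0926) and Dbp (0.0625), at 9 h against 0.5 h for Fkbp5 (-0.0258), and at 9 h against 6 h for Fos (-0.1424) and Gap43 (-0.0392). Capped normexp turned Gap43 at 6 h against 0.5 h (0.0511) and Fos at 9 h against 6 h (-0.0305), and cyclic loess Gap43 at 6 h against 0.5 h (0.0208). Leaving out 1 array turned Fos at 3 h (-0.503 to 0.1018), 6 h (-0.1221 to 0.4826) and 9 h (-0.0555 to 0.5493) against 0.5 h and at 9 h against 6 h (-0.1423 to 0.3293). At 6 h against 0.5 h it turned Atf3 (-0.2882 to 0.2064), Gal (-0.1521 to 0.035), Npy (-0.9952 to 0.0385), Gap43 (-0.0597 to 0.0353) and Dbp (-0.0796 to 0.02), and at 9 h against 0.5 h Fkbp5 (-0.0887 to 0.1841). At 6 h against 3 h it turned Jun (-0.0188 to 0.0832), Npy (-0.2001 to 0.7589) and Il6 (-0.3251 to 0.0193), and at 9 h against 6 h Gal (-0.1373 to 0.0498) and Npy (-0.8263 to 0.1327). The cause was not tested.

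With the replicate number as a block the counts were 5675, 3256, 8909, 2475, 6693 and 11100, with 6 list calls. The numbers do not pair the arrays: 3 of 18 same-number pairs correlated above 0.1 (range -0.133 to 0.223), and 4 of 12 arrays correlated best with their own number. The deposited series-wide table holds the same values, so it was not fitted again and its counts are the same by construction. Signal over background limits the 0.5 h comparisons most, since the lowest signal well above background was 57.6 to 73.3 units there and 11.3 to 18.3 on the other arrays.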

Other observations

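The test of other probes and the test of scaling on the glucocorticoid list were chosen only after the results were seen. Between 6 and 9 h further groups had called members. Of 24 glucocorticoid targets 5 rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.661), of 19 pan-neuronal genes 3 rose (2 adjusted over the list alone) and of 34 sensory neuron channels and receptors 4 rose and 1 fell (2 up adjusted over the list alone). Of 15 lymphocyte markers 3 rose and of 7 adipocyte markers 2 rose, the same when adjusted over the list alone. Of 16 clock genes 4 rose and 4 fell (5 and 4 adjusted over the list alone).

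A set of 917 genes, 3.10% of those tested, fell by 3 h, rose by 6 h and fell by 9 h, while 128 took the opposite course. Of the 917, 145 had a gene symbol and the others only a placeholder name. For the genes of this set with another kept probe, a change of transcripts as a whole is argued against, since the median change of their 61 other probes from 3 to 6 h was -0.1043 (quartiles -0.19 to 0.10) against 0.513 for the chosen probes, although 11 of 61 followed in all 3 steps, against 5 of 15 for other genes called in each step (Fisher's exact test, two-sided, p = 0.286). The chosen probes were picked for this course in the same data, so their 0.513 may be overstated. The other probes cover only a small part of the set. Scaling is argued against as the cause, since at least 831 of the genes kept the course under quantile, median and cyclic loess scaling. Base composition of the probes may contribute, since the share was 5.64% in the fifth of probes with the lowest G and C content and 1.70% in that with the highest, a ratio of 3.307. A change of single transcript isoforms stays open as an untested hypothesis.

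The glucocorticoid targets, of which 11 of 24 rose by 3 h and 12 fell from 3 to 6 h, were weighed against tissue mixture and scaling. Muscle or fat in the dissected tissue is argued against as the whole cause, since with marker levels of both in the fit the list's median from 0.5 to 3 h, when muscle and fat medians were 1.28 and 1.03, was 0.47 (median SE 0.176, camera adjusted p = 0.00415), against 0.51 without them. From 3 to 6 h it was -0.681 (median SE 0.159), against -0.62, but muscle and fat medians moved little over that step (0.11 and -0.19). Scaling is argued against as the source of the camera calls, since the highest adjusted p of the list in both comparisons under quantile, median and cyclic loess scaling was 0.0178. At 3 h against 0.5 h the camera values are weak evidence. In the reported fit, 4 of 10 splits of those 6 arrays gave as small an adjusted p as the real one. A hormone response to surgery or anaesthesia may underlie the course, but this was not tested. Slide differs with time after injury, and time of day and handling may do so too, which was also not tested.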
